A study of Mus musculus with 11 samples.

How the data were processed

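Messenger RNA was sequenced from macrophages sorted out of mammary tumours of control-PyMT and MYC-PyMT female mice, in 11 libraries from 6 mice. Per the labels, the cells were sorted as CD45 positive and negative for SiglecF, Ly6G, B220 and Ly6C, then by F4/80, Vcam and FOLR2. Libraries were made from 500 ng of RNA with integrity numbers from 3.3 to 9.6, by poly-A selection, a stranded kit and 8 PCR cycles. Each library is a separate sort, and the number in its label is the mouse. Per the submitters' processing notes, the reads were mapped with HISAT2 to mm10 (GRCm38.p5) and DESeq2 was used; the notes give no role for it.

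The deposited table holds 17475 genes, with values the authors gave as log2 expression. Their formula was inferred from the values and is not stated. The values behaved as the log2 of x plus 1.00, where x is a read number scaled for depth and divided by gene length. Within a library the lowest values were evenly spaced, as whole reads are. All of 10701 low values tested were whole multiples of 1 read within a tolerance of 0.05. Genes without a read in a library shared 1 floor per gene. The spacing gave each library's depth relative to the others, from 0.836 to 1.07, and with exon lengths from the GENCODE annotation of GRCm38 (found for 93.5% of genes) about 33.0 to 43.7 M reads (M for mega) in genes. These depths are estimates and cover counting error only. A read at a gene of 1 kb of exons was worth about 0.0370 on the scale of x. For a gene without reads in every library of a group, a bound was computed at 3 reads per library. There were 26 entries whose names had been turned into dates or numbers by a spreadsheet and 64 that shared a symbol with another. They stayed in the tests and were not named.

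Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with a mean for each of the 4 groups was fitted to the deposited values of all 11 libraries, with moderated variances that follow a trend with level, and without a block for the mouse. The tests were two-sided and adjusted by Benjamini-Hochberg over the 17475 genes, with a threshold of 0.05. The 5 comparisons were TAMs minus MTMs in control and in MYC mice, MYC minus control in TAMs and in MTMs, and the difference of the cell type difference between the genotypes. The minimum mean of 0 planned for this unit removed no gene, so that filter was void. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the depths and the figures. Principal components used all 17475 genes, centred and not scaled.

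The labels give the pairing of TAMs and MTMs by mouse. Checked on the values, the deviations from the group means correlated across genes at 0.157, 0.184 and 0.0685 in the control pairs and 0.109 and 0.0523 in the MYC pairs, and the correlation estimated by limma for libraries of a mouse was 0.127. Control libraries of different mice correlated at -0.167 to 0.00687. The MYC pairs cannot check the pairing, as deviations of 2 MYC MTM libraries mirror each other. There TAM mouse 6 and MTM mouse 4 correlated at 0.0544. Models with the mouse as a fixed or a random block were alternatives, and their counts stand beside the main ones. Replicates of a group were not copies of each other: over 1729 genes with a mean of 5 or more, the SD of their log2 difference was 0.369 to 0.815, and 0% of values were identical.

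Gene lists were tested with camera (limma) against all other genes, with a preset correlation of 0.01, and again with a correlation estimated from the data. Adjustment was over the 35 lists of a comparison. The lists were 36 in number and fixed before the data were examined, and 35 could be tested, as no mitochondrially encoded gene was measured. They cover macrophage programmes, metabolism, and markers of the other cell types that a gate could let through. Some genes are on more than 1 list, so the lists are not independent of each other. Of 948 list members 58 were not measured, and 11 were matched through an older symbol. Of the 35 lists, 24 passed in at least 1 comparison. The other 11 passed in none, although some did under alternatives, and their smallest adjusted p over the 5 comparisons was 0.0585 for fibroblast markers, 0.0620 for PIKfyve machinery, 0.0725 for B and plasma cells, 0.0927 for matrix proteases, 0.111 for eosinophils and mast cells, 0.123 for endothelium, 0.315 for erythroid cells, 0.330 for Rag GTPase and TFEB/TFE3 machinery, 0.399 for neutrophils, 0.412 for iron handling and 0.692 for oxidative phosphorylation.

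Genes were named by a rule fixed before the data were examined. Per comparison it took up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold whose libraries did not overlap between the groups (overlap was not asked of the difference of differences), leaving out unnamed gene models. It added up to 4 members with the smallest adjusted p from each passing list, the genes of the sort gate, Myc and S100a8, and Tfeb, Tfe3, Flcn, Rragd, Gpnmb, Sqstm1 and Pikfyve. Siglecf and Ly6g were not analysed here. The Y-linked genes, the pan-macrophage genes and the list members named in the report outside this rule (Itgam, Cd300lb, Olr1, Itgax and Ctss in MYC against control TAMs, Atg7, Gnl3, Naaa, Man2b1, Gm2a, Ctsf and Scarb2) were chosen after their values were seen. The other observations name further members chosen so and say which.

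The method was tested on simulated data of the same size and spread, with 100 genes changed by a log2 of 1 and 100 by 2. At 1 it recovered 38%, 37%, 30%, 20% and 6% of them in the 5 comparisons, in the order above, and at 2 it recovered 84%, 82%, 87%, 82% and 47%. Of the genes it called, 3.85%, 6.06%, 4.76%, 8.70% and 6.90% had not been changed. The changed genes had a mean of 1 or more, and the vacuolar ATPase subunits were raised by 1 as well. The simulated noise was normal and independent between genes. These shares need not hold where genes correlate or many more of them change.

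The groups, the comparisons, the model and most alternatives were chosen before the data were examined. These alternatives were quantile normalisation, centring each library on its median, adding 8 before the logarithm, a mean of 2 or more, no filter, no trend, weights per library, a fit of only the groups compared (without the genes that had the same value in all of its libraries), the mouse blocks, the estimated correlation and leaving out each library in turn. Chosen after seeing the data were a mean of 1 or more, the mean of the epithelial markers as a covariate, and leaving out the MYC TAM libraries of mice 4 and 6 together. Mouse 4 had few genes without reads, and mouse 6 had the lowest epithelial level. An effect of the diet was not tested, as every library was on the low protein diet. Batches of sorting or sequencing are not given by the labels.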

Results

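Macrophages were sorted from mammary tumours of 6 female mice and their messenger RNA was sequenced. All mice carried PyMT, a viral oncogene that drives mammary tumours. The MYC mice also carried Cre under the S100a8 promoter and a MYC transgene that Cre switches on, and the series calls their tumours MYC overexpressing. The mice were irradiated at 7 weeks of age, given 3 M wild-type bone marrow cells, and fed a low protein diet for 6 weeks starting 2 weeks later. Tumour-associated macrophages of the parenchyma (TAMs) were gated as F4/80 and Vcam positive, and mammary tissue macrophages of the stroma (MTMs) as Vcam negative and FOLR2 positive. There were 11 libraries, namely 3 of control TAMs, 3 of control MTMs, 3 of MYC TAMs and 2 of MYC MTMs. Every library was on the low protein diet, so an effect of diet could not be tested. The odd-numbered mice 1, 3 and 5 were controls and the even-numbered mice 2, 4 and 6 were MYC, and 5 of the 6 mice gave both cell types.

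Depth was estimated from the spacing of the lowest values. In the order of the mouse numbers, about 37.0, 39.4 and 37.9 M reads (M for mega) fell in genes in the control TAM libraries, and 37.0, 39.9 and 36.2 M in the control MTM libraries. The MYC TAM libraries had 43.7, 33.0 and 41.6 M, and the MYC MTM libraries 38.9 and 39.0 M. In the MYC TAM library of mouse 4, 581 genes had no read, against 2072 to 3522 in the other libraries. All levels below are on the deposited log2 scale, in which the number of reads was scaled for depth and gene length before the logarithm. Values are group mean ± SD. Differences are log2 differences ± SE from limma, with 3 libraries per group except for MYC MTMs (n = 2). Folds are 2 to the power of these differences.

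Principal components placed genotype on the first axis (40.4% of the variance) and cell type on the second (19.1%). The MYC TAM libraries lay from 51.0 to 68.9 on the first axis and the MYC MTM libraries at 9.49 and 6.35, while the control libraries lay from -46.7 to -23.8. The gene of the FOLR2 gate separated the cell types in both genotypes. Folr2 (chromosome 7, 101839988 to 101857194, minus strand, GRCm38) was at 1.37 ± 0.41 in control TAMs and 7.83 ± 0.19 in control MTMs, and at 2.04 ± 1.38 in MYC TAMs and 8.26 ± 0.27 in MYC MTMs. Vcam1, the gene of the other gate, did not separate them in the MYC mice. Vcam1 (chromosome 3, 116109949 to 116129688, minus strand) was at 8.27 ± 0.54 in control TAMs and 5.80 ± 0.91 in control MTMs, but at 1.80 ± 0.95 in MYC TAMs and 2.32 ± 0.01 in MYC MTMs. Neither Vcam1 difference between the cell types passed the threshold (adjusted p = 0.0501 in controls and 0.693 in MYC). Emr1, the older symbol of Adgre1, which encodes F4/80, was at 9.63 ± 0.27 in control TAMs, 9.70 ± 0.23 in control MTMs, 7.82 ± 0.48 in MYC TAMs and 9.89 and 9.88 in the MYC MTM libraries. Ly6c2, of the negative Ly6C gate, was at 0.07, 0.20 and 0.07 in MYC TAMs and 1.29 and 0.96 in MYC MTMs. That difference passed but was lost under 5 of 22 alternatives. Ptprc, which encodes CD45, passed between MYC and control TAMs and was lost under 5 of 23 alternatives. Myc itself was at 2.98 ± 0.28 in control TAMs and 1.95 ± 0.19 in MYC TAMs, and at 2.63 ± 0.11 in control MTMs and 2.94 ± 0.11 in MYC MTMs, where the libraries did not overlap but the difference did not pass (0.31 ± 0.21, adjusted p = 0.733). Of all genes 31.2% did not overlap between these MTM groups, and 20% would by chance, so the lack of overlap says little about Myc.

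**Figure D1:**
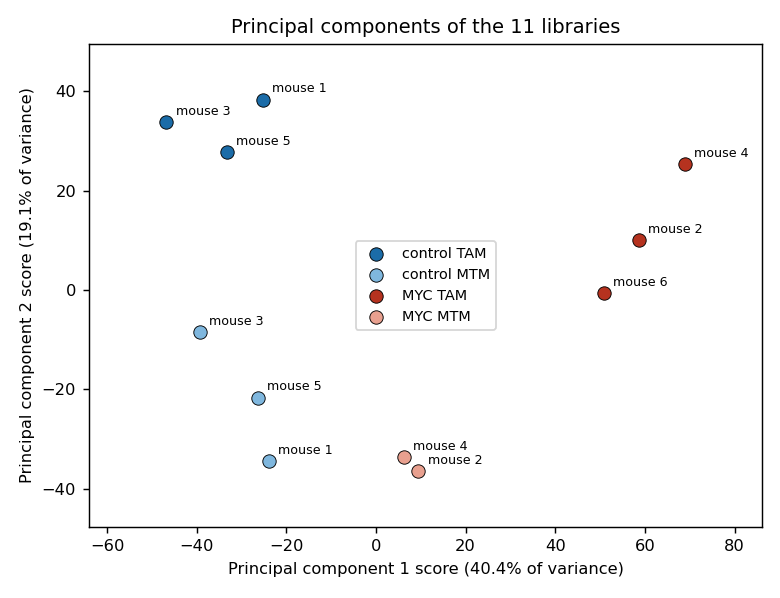
Principal components of the 11 libraries on the deposited log2 values, with the first component (40.4% of the variance) across and the second (19.1%) up; each point is a library, coloured by group. The MYC TAM libraries lie from 51.0 to 68.9 on the first axis, apart from all other groups.

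Control TAMs and control MTMs were compared to ask how the macrophages of the tumour parenchyma differ from those of the mammary stroma. Control MTMs carried far more RNA of the genes that mark tissue-resident and alternatively activated macrophages. Retnla, a secreted product of alternatively activated macrophages, was at 13.54 ± 0.39 in MTMs and 5.17 ± 0.07 in TAMs, a difference of -8.37 ± 0.76 (331-fold, adjusted p = 0.000506). F13a1, a coagulation factor chain made by resident macrophages, differed by -7.58 ± 0.35 (191-fold), the lectin gene Cd209f by -6.75 ± 0.27 (108-fold) and the haemoglobin scavenger receptor gene Cd163 by -5.54 ± 0.51 (46.6-fold). TAMs had more of H2-M2, a non-classical MHC gene (4.19 ± 0.37), Adamdec1, a metalloprotease (3.74 ± 0.38), Il1r2, the decoy receptor of interleukin-1 (3.32 ± 0.46), and Itgax, which encodes CD11c (2.28 ± 0.31).

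Of the 32 measured tissue-resident macrophage genes, 21 were lower in control TAMs than in control MTMs and none was higher (22 lower adjusted over the list alone). The list's median was -2.78 (camera adjusted p = 4.47e-35), and its call held with an estimated correlation (adjusted p = 0.00841). Of 21 alternative activation genes 9 fell (14 adjusted over the list alone; median -1.42, adjusted p = 1.59e-17, and adjusted p = 0.0218 with an estimated correlation). Examples are the chemokine gene Ccl24 (-4.65 ± 0.28), the lectin gene Clec10a (-3.72 ± 0.30) and Ear2 (-4.56 ± 0.35). This list shares Mrc1, Ccl24, Clec10a, Mgl2 and Cd163 with the tissue-resident list, and the complement list shares Vsig4 with it. The results of these lists are therefore not independent. Complement genes fell too, 5 of 18 (7 adjusted over the list alone; median -0.29, adjusted p = 2.00e-05, and adjusted p = 0.0218 with an estimated correlation). They included properdin (Cfp, -4.13 ± 0.36), C4b (-3.17 ± 0.37) and the integrin gene Itgam (-1.56). The complement receptor gene Vsig4 had no read in any control TAM library and was at least 11.3-fold lower there, with 3 reads per library as the floor. The lipid-associated gene Gpnmb was lower in control TAMs (-3.11 ± 0.40, adjusted p = 0.00336).

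The remaining lists that passed in controls had few members past the threshold, and none held with an estimated correlation. T and NK cell markers were higher in TAMs by a median of 0.62 (adjusted p = 1.34e-10, and adjusted p = 0.312 with an estimated correlation), although over all genes the only member to pass was Cd2, which fell (-2.82 ± 0.46). Adjusted over the list alone, 12 of 23 rose and 1 fell. MHC class II genes had a median of 0.76 (adjusted p = 0.000242, and adjusted p = 0.344 with an estimated correlation), with H2-Oa higher (2.28 ± 0.28) and the costimulator gene Cd80 lower (-0.84 ± 0.18). Engulfment receptors had 1 member higher and 5 lower of 28 (median -0.15, adjusted p = 0.0168, and adjusted p = 0.727 with an estimated correlation), with Itgb5 higher (0.87 ± 0.14) and Timd4 (-2.35 ± 0.20), Scarf1 (-1.66 ± 0.27), Pros1 (-1.53 ± 0.19), Cd300lb (-1.59) and Olr1 (-1.06) lower. MYC targets (median 0.26, adjusted p = 8.56e-06), ribosomal proteins (0.45, 7.08e-05), epithelial markers (0.37, 0.0143), ATF4 targets (0.13, 0.0302) and proliferation genes (-0.24, 0.0336) passed as lists with no single member past the threshold, and their adjusted p with an estimated correlation was 0.283 to 0.792.

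Over all genes, 414 of 17475 differed between control TAMs and control MTMs, 130 higher and 284 lower in TAMs (limma, adjusted p below 0.05). With the mouse as a fixed block the count was 255, and as a random block 542. Of the 34 named genes that passed, 30 passed without each library in turn; Cd2, Cd80, Itgb5 and Scarf1 did not. Cd2 was lost without control TAM mouse 3 (adjusted p = 0.0527) or 5 (0.0515) or control MTM mouse 1 (0.0569) or 5 (0.0554). Cd80 was lost without any control library (0.0936 to 0.151), MYC TAM mouse 4 (0.0599), or MYC MTM mouse 2 (0.0610) or 4 (0.0591). Itgb5 was lost without control TAM mouse 1 (0.0596) or 3 (0.0594) or control MTM mouse 1 (0.0566) or 5 (0.0565), and Scarf1 without control TAM mouse 1 (0.0602) or control MTM mouse 1 (0.0566) or 5 (0.0579). The count was 216 without control TAM mouse 1, 242 without control MTM mouse 1 and 217 without control MTM mouse 5. Among the lists, proliferation lost its call without control TAM mouse 1 (adjusted p = 0.577), control MTM mouse 3 (0.840), MYC TAM mouse 4 (0.0677) or MYC TAM mouse 6 (0.0581). The ATF4 list lost it without control TAM mouse 3 (0.222), control MTM mouse 1 (0.164) or control MTM mouse 5 (0.0699), epithelial markers without control TAM mouse 3 (0.279) or control MTM mouse 1 (0.0542), and engulfment receptors without control TAM mouse 3 (0.0841). Under alternatives chosen after seeing the data, engulfment receptors (0.0665), ATF4 targets (0.0905) and proliferation (0.163) lost it among genes with a mean of 1 or more, engulfment receptors (0.246) with the epithelial level of each library as a covariate, and proliferation (0.0926) without MYC TAM mice 4 and 6. With the covariate lysosomal genes passed upward (median 0.12, adjusted p = 0.00195).

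The same comparison in the MYC mice asks how the cell types differ in tumours that overexpress MYC. As in controls, MTMs had more Retnla (9.66 ± 1.79 against 1.54 ± 1.51 in TAMs; -8.12 ± 0.85, 278-fold), Folr2 (-6.22 ± 0.62), the matrix glycoprotein gene Fn1 (-5.81 ± 0.67), Lyve1, a hyaluronan receptor (-5.76 ± 0.44), and Cd163 (-5.36 ± 0.57). The acute phase gene Saa3 was 54.0-fold lower in TAMs (-5.75 ± 0.69). Tissue-resident genes fell in 21 of 32 members (26 adjusted over the list alone; median -2.87, adjusted p = 6.54e-27, and adjusted p = 0.00949 with an estimated correlation). Complement genes fell in 9 of 18 (13 adjusted over the list alone; median -1.28, adjusted p = 1.35e-11, and adjusted p = 0.00540 with an estimated correlation), for example factor B (Cfb, -4.04 ± 0.34) and C2 (-2.54 ± 0.29). Cd209d had no read in any MYC TAM library and was at least 22.1-fold lower there, on the same floor of 3 reads per library.

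Genes of dividing cells were lower in MYC TAMs than in MYC MTMs. Of 33 proliferation genes 28 fell and none rose over all genes tested (30 fell and 1 rose adjusted over the list alone). Their median was -1.62 (adjusted p = 1.93e-26, and adjusted p = 0.108 with an estimated correlation). Examples are cyclin B2 (Ccnb2, -3.12 ± 0.34), the ribonucleotide reductase subunit Rrm2 (-2.85 ± 0.28), Plk1 (-2.65 ± 0.28) and Kif20a (-2.61 ± 0.32). The mean level of these genes was 2.46, 2.42 and 2.32 in the MYC TAM libraries, against 4.01 and 4.13 in the MYC MTM libraries. Epithelial markers moved the same way, with a mean level of 3.49, 2.48 and 1.46 in the MYC TAM libraries and 3.52 and 3.76 in the MYC MTM libraries. The epithelial list fell as a whole (median -0.99, adjusted p = 0.000379, and adjusted p = 0.528 with an estimated correlation), with 2 of 30 members past the threshold, E-cadherin (Cdh1, -2.19 ± 0.38) and transferrin (Trf, -1.08 ± 0.22). Without the MYC TAM libraries of mice 4 and 6 its median was 0.00 (adjusted p = 0.483).

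Vacuolar ATPase subunits, which acidify lysosomes, had a median of 0.47 in MYC TAMs over MTMs (adjusted p = 2.88e-06, and adjusted p = 0.0332 with an estimated correlation), and 2 of 17 rose (7 adjusted over the list alone), namely Atp6v0d2 (1.56 ± 0.35) and Atp6v1c1 (1.00 ± 0.19). Lipid-associated macrophage genes rose in 6 of 23 members and fell in 1 (10 and 1 adjusted over the list alone; median 0.73, adjusted p = 4.80e-08, and adjusted p = 0.0723 with an estimated correlation). The rises included the lectin gene Clec7a (2.07 ± 0.30), Itgax (1.97 ± 0.34) and Gpnmb (2.30 ± 0.45), and lipoprotein lipase fell (Lpl, -2.98 ± 0.37). Other genes higher in MYC TAMs were Cdo1, which degrades cysteine (3.79 ± 0.54), Lrrc27 (2.46 ± 0.18) and the receptor gene Klra3 (2.16 ± 0.26). Alternative activation genes fell in 9 of 21 (median -0.91, adjusted p = 1.69e-05, and adjusted p = 0.146 with an estimated correlation). Monocyte markers fell in 6 of 18 (median -0.60, adjusted p = 0.000262, and adjusted p = 0.0696 with an estimated correlation), among them the chemokine receptor genes Ccr2 (-3.36 ± 0.38) and Cx3cr1 (-2.72 ± 0.25).

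Other lists passed the camera test in this comparison but not with an estimated correlation (adjusted p from 0.146 to 0.674). ATF4 targets (median -0.50, adjusted p = 3.69e-05), MHC class II (-1.09, 0.000232), NF-kB mediators (-0.72, 0.000350), glycolysis and hypoxia (-0.54, 0.000357), dendritic markers (-0.35, 0.00130), interferon response (-0.45, 0.00287), MYC targets (-0.33, 0.00287), engulfment receptors (-0.43, 0.00936) and dissociation genes (-0.48, 0.0461) were lower in MYC TAMs. Ribosomal proteins (0.45, adjusted p = 0.000156) and lysosomal genes (0.14, 0.00215) were higher. Single libraries decided some of these. The mean level of ribosomal proteins was 7.63, 7.00 and 6.34 in the MYC TAM libraries of mice 2, 4 and 6, against 6.51 and 6.52 in the MYC MTM libraries. Ribosomal proteins lost the call without MYC TAM mouse 2 (adjusted p = 0.745), lysosomal genes without MYC TAM mouse 6 (0.251), MYC targets without MYC TAM mouse 4 (0.05004), and engulfment receptors without MYC TAM mouse 2 (0.0685) or mouse 4 (0.185). The interferon list lost it without MYC TAM mouse 2 (0.0685) or mouse 4 (0.342) or MYC MTM mouse 4 (0.125). Dissociation genes lost it without control TAM mouse 3 (0.0513), control MTM mouse 1 (0.0716), MYC TAM mouse 4 (0.487) or 6 (0.108), or MYC MTM mouse 4 (0.192). Alternatives chosen after seeing the data ended other calls. Among genes with a mean of 1 or more these were engulfment receptors (0.287), MYC targets (0.256), NF-kB mediators (0.0845), interferon response (0.146), dissociation genes (0.344) and monocyte markers (0.0628). With the epithelial covariate, whose levels did not overlap between MYC TAMs and MTMs, they were lysosomal genes (0.522), MYC targets (0.351) and dissociation genes (0.416), while oxidative phosphorylation (median 0.34, adjusted p = 0.000377), PIKfyve machinery (-0.15, 0.00943) and matrix proteases (-0.25, 0.0332) passed with it. Without MYC TAM mice 4 and 6 they were MYC targets (0.540), NF-kB mediators (0.188), dissociation genes (0.775) and the epithelial markers given above.

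In the MYC mice 784 genes differed between the cell types, 116 higher and 668 lower in TAMs. The share higher was 14.8%, but 29.9% after quantile normalisation (171 higher, 400 lower) and 35.8% after centring each library on its median (207 higher, 372 lower), which moved the median of all genes to 0.15. With the mouse as a fixed block the count was 476, and as a random block 972. The 2 MYC MTM libraries weighed heavily, since the count was 163 without mouse 2 and 226 without mouse 4. Of the 78 named genes that passed, 30 did so without each library in turn, and 45 lost the call without MYC MTM mouse 2, with adjusted p up to 0.334, and 42 without MYC MTM mouse 4, up to 0.289. Among the genes named above, the calls that were lost were those of Gpnmb (0.215 without MYC MTM mouse 2), Atp6v0d2 (0.334), Atp6v1c1 (0.200), Clec7a (0.0801), Itgax (0.108), Cdh1 (0.100) and Trf (0.165). Leaving out MYC MTM mouse 4 also ended those of Gpnmb (0.0843), Atp6v0d2 (0.0791), Atp6v1c1 (0.0843), Cdh1 (0.0990) and Trf (0.168). Gpnmb and Trf were lost too without MYC TAM mouse 2 (0.0535 and 0.0650), and Atp6v0d2 without MYC TAM mouse 2 (0.0669), 4 (0.0929) or 6 (0.0682), control TAM mouse 1 (0.0553) or 3 (0.0563), or control MTM mouse 5 (0.0584).

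The difference between TAMs and MTMs was shared in part between the genotypes. Of the 284 genes lower in control TAMs, 125 were also lower in MYC TAMs, where 10.9 would be shared if the sets were independent. Of the 130 higher in control TAMs, 6 were also higher in MYC TAMs, against 0.863, and 7 were lower. Of the 284, 6 were higher in MYC TAMs. The sets rest on the same variance estimate per gene, which can raise the number shared above that of independent sets. Across 9375 genes with a mean of 1 or more, the differences correlated with Pearson's r = 0.354 and Spearman's rho = 0.185. These are correlations across genes, which are not independent replicates.

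**Figure D2:**
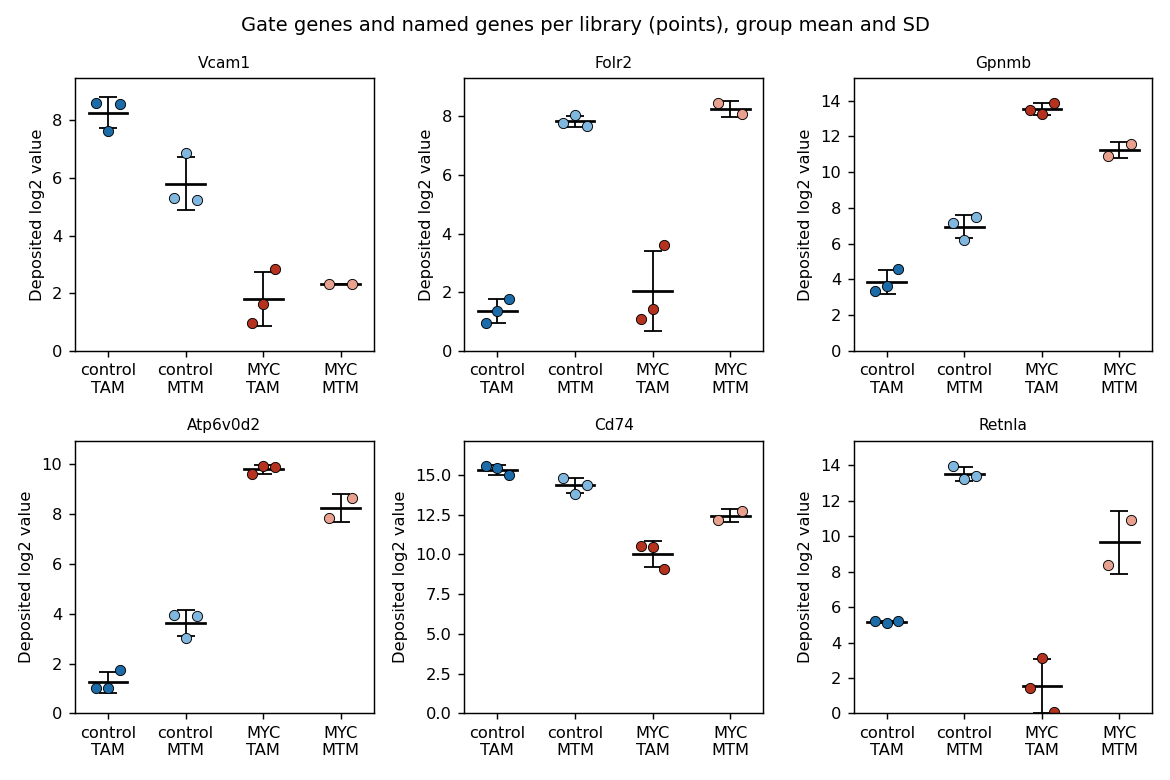
Deposited log2 level of 6 genes in each of the 11 libraries; points are libraries, bars the group mean and SD (n = 3, and n = 2 for MYC MTMs). Folr2 and Retnla separate TAMs from MTMs in both genotypes, while Vcam1 is lower and Gpnmb and Atp6v0d2 higher in MYC than in control libraries of both cell types.

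TAMs of MYC tumours and of control tumours were compared to ask how these macrophages differ when the tumour overexpresses MYC. The largest rise among the named genes was in Gpnmb, a lysosomal and surface glycoprotein gene of lipid-laden macrophages (chromosome 6, 49036546 to 49070929, plus strand). It rose from 3.84 ± 0.66 in control to 13.53 ± 0.31 in MYC TAMs, by 9.69 ± 0.40 (827-fold, adjusted p = 2.21e-06). Atp6v0d2, a vacuolar ATPase subunit gene (chromosome 4, 19876841 to 19922605, minus strand), rose from 1.25 ± 0.43 to 9.81 ± 0.19, by 8.56 ± 0.32 (377-fold, adjusted p = 1.33e-06). Chi3l3, the older symbol of Chil3, a chitinase-like protein gene, rose by 7.62 ± 0.60, the fatty acid binding protein gene Fabp4 by 7.33 ± 0.43, heparanase (Hpse) by 6.57 ± 0.33 and cathepsin K (Ctsk) by 6.46 ± 0.63. Vcam1 fell by 6.47 ± 0.54 (88.9-fold), the prostaglandin synthase gene Ptgs1 by 5.66 ± 0.21, the collagenase gene Mmp13 by 5.39 ± 0.55 and Cd74, the MHC class II invariant chain, by 5.30 ± 0.45 (39.5-fold).

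Lists of lipid-associated, vacuolar ATPase, lysosomal and autophagy genes passed upward in MYC TAMs. Lipid-associated macrophage genes rose in 14 of 23 members and fell in 2 (16 and 2 adjusted over the list alone; median 1.34, adjusted p = 5.03e-11, and adjusted p = 0.0739 with an estimated correlation). They included galectin-3 (Lgals3, 2.60 ± 0.18) and cathepsin L (Ctsl, 2.87 ± 0.43), whereas Lpl fell by 3.60 ± 0.33 and Itgax fell by 1.44. Of 17 vacuolar ATPase subunits 8 rose and none fell (10 rose adjusted over the list alone; median 0.78, adjusted p = 1.70e-07, and adjusted p = 0.0573 with an estimated correlation), for example Atp6v1c1 (1.75 ± 0.17) and Atp6v1g1 (1.45 ± 0.20). Of 51 lysosomal genes 19 rose and 5 fell (21 and 5 adjusted over the list alone; median 0.50, adjusted p = 3.07e-06, and adjusted p = 0.247 with an estimated correlation), with Gla (2.29 ± 0.22), Cd68 (1.95 ± 0.15) and Smpd1 (1.17 ± 0.16) among the rises, and Man2b1 (-1.23), Gm2a (-1.16), Ctsf (-0.90) and Scarb2 (-0.54) among the falls. Of 28 autophagy genes 5 rose (5 adjusted over the list alone; median 0.20, adjusted p = 0.00182, and adjusted p = 0.124 with an estimated correlation), namely the mitophagy receptor gene Bnip3l (2.02 ± 0.22), Optn (2.08 ± 0.31), Gabarapl1 (1.89 ± 0.20), Atg12 (0.98 ± 0.14) and Atg7 (0.84). The lysosomal calcium channel gene Mcoln3 rose by 5.32 ± 0.44.

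Genes of antigen presentation and cell division were lower in MYC TAMs. Of 14 MHC class II genes 11 fell and 1 rose (12 and 1 adjusted over the list alone; median -2.80, adjusted p = 5.71e-08, and adjusted p = 0.153 with an estimated correlation). H2-Eb1 fell by 5.08 ± 0.45, H2-DMa by 3.10 ± 0.23 and H2-Oa by 2.98 ± 0.28, and cathepsin S rose (Ctss, 0.90 ± 0.19). Of 33 proliferation genes 29 fell and none rose (32 fell adjusted over the list alone; median -1.81, adjusted p = 5.10e-18, and adjusted p = 0.247 with an estimated correlation), with Rrm2 (-2.71 ± 0.25), Plk1 (-2.49 ± 0.25) and Aurka (-1.81 ± 0.20) among them. Of 28 NF-kB mediators 12 fell (15 adjusted over the list alone; median -0.85, adjusted p = 0.000101, and adjusted p = 0.481 with an estimated correlation), including Il1b (-4.46 ± 0.54) and Il12b (-2.42 ± 0.44). Of 41 interferon response genes 9 fell (12 adjusted over the list alone; median -0.68, adjusted p = 2.87e-05, and adjusted p = 0.587 with an estimated correlation), including Cxcl10 (-2.86 ± 0.40) and Gbp3 (-1.40 ± 0.24).

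Lists of ATF4 targets, MYC targets and cholesterol synthesis genes passed downward. Of 35 ATF4 targets, which respond to amino acid shortage, 13 fell (16 adjusted over the list alone; median -0.65, adjusted p = 0.000169, and adjusted p = 0.324 with an estimated correlation), for example the amino acid transporter gene Slc7a5 (-2.11 ± 0.31) and Aldh18a1 (-2.16 ± 0.27). Of 40 MYC targets 11 fell and 1 rose (15 and 1 adjusted over the list alone; median -0.42, adjusted p = 0.00130, and adjusted p = 0.324 with an estimated correlation), the rise being in Gnl3 (0.82), and Myc fell by 1.02 ± 0.19 (adjusted p = 0.00583). Of 24 cholesterol synthesis genes 3 fell, among them Hmgcs1 (-1.08 ± 0.28) and Dhcr7 (-1.18 ± 0.33). Adjusted over the list alone, 12 fell and 1 rose (median -0.54, adjusted p = 0.00252, and adjusted p = 0.465 with an estimated correlation). Ribosomal proteins had a median of 0.29 (adjusted p = 0.00441, and adjusted p = 0.779 with an estimated correlation), which became -0.12 without MYC TAM mouse 2 (adjusted p = 0.779), and the adjusted p was 0.0818 after quantile normalisation. With the epithelial covariate described below the median was larger, at 2.02 (adjusted p = 3.44e-22). That covariate did not overlap between control and MYC TAMs, so this value is an extrapolation. In MYC TAM mice 2, 4 and 6 the ribosomal mean (7.63, 7.00 and 6.34) fell with the epithelial level (3.49, 2.48 and 1.46).

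Markers of other cell types moved with the genotype. Epithelial markers fell in 18 of 30 members (22 adjusted over the list alone; median -2.30, adjusted p = 1.70e-07, and adjusted p = 0.324 with an estimated correlation). Their mean level was 4.51, 5.25 and 4.42 in the control TAM libraries and 3.49, 2.48 and 1.46 in the MYC TAM libraries. T and NK cell markers fell in 15 of 23 and 1 rose, the receptor gene Il7r (3.41 ± 0.32). The list had 17 lower and 1 higher adjusted over the list alone, with a median of -1.07 (-0.95 with members without reads in a group at their floor; adjusted p = 1.28e-06, and adjusted p = 0.324 with an estimated correlation). Dendritic cell markers fell in 10 of 22 and 1 rose (11 and 1 adjusted over the list alone; median -0.44, adjusted p = 0.000534, and adjusted p = 0.247 with an estimated correlation), with Batf3 at -2.40 ± 0.22 and the rise in Naaa (0.94). With the epithelial level of each library as a covariate, chosen after seeing the data, the lists for proliferation (median -1.22, adjusted p = 1.61e-08), lipid-associated genes (1.59, 9.89e-07), vacuolar ATPase (0.75, 0.000226), MHC class II (-2.54, 4.23e-06) and interferon response (-0.99, 4.49e-06) still passed, and those for lysosomal genes (0.20, 0.310), ATF4 targets (-0.39, 0.0693) and MYC targets (-0.13, 0.919) did not. Lists that had not passed without it and did with it were oxidative phosphorylation (0.56, 4.49e-06), complement (-0.71, 0.0158) and engulfment receptors (-0.41, 0.00976). Its levels did not overlap between control and MYC TAMs, so all values with the covariate are extrapolations. The covariate also ended the calls of Ctsl (0.275), Slc7a5 (0.285), Aldh18a1 (0.0566), Plk1 (0.0532), Il1b (0.0912), Il12b (0.226), Cxcl10 (0.188), Gbp3 (0.0529), Dhcr7 (0.0517), Myc (0.399) and Rragd (0.0780). Y-linked genes, chosen after their values were seen, also moved with genotype. Ddx3y was at most 0.06 in every control library and at 4.37, 4.74 and 4.50 in the MYC TAM libraries.

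Between control and MYC TAMs 2778 genes differed, 680 higher and 2098 lower in MYC. The share higher depended on scaling. It was 24.5% on the deposited values, 41.6% after quantile normalisation (1107 higher, 1553 lower) and 69.9% after median centring (3516 higher, 1513 lower), which moved the median of all genes to 0.19. No passing list's median and none of the named genes that passed changed sign under either scaling. The mouse as a random block gave 2813 genes. Without control TAM mouse 3 the count was 1734, and of the 76 named genes that passed 67 passed without each library in turn. Of those named in these paragraphs, the exceptions were Dhcr7 and Hmgcs1. Dhcr7 was lost without control TAM mouse 1 (adjusted p = 0.0545), 3 (0.0890) or 5 (0.131), control MTM mouse 1 (0.0562), 3 (0.0513) or 5 (0.0542), MYC TAM mouse 2 (0.112) or 4 (0.104), or MYC MTM mouse 2 (0.0618) or 4 (0.0615). Hmgcs1 was lost without control TAM mouse 3 (0.0895) or 5 (0.0970) or MYC TAM mouse 2 (0.0680) or 4 (0.0606). Without both MYC TAM libraries of mice 4 and 6 the calls of Il12b (0.0614), Myc (0.0733), the NF-kB list (0.0667) and MYC targets (0.329) ended. Among genes with a mean of 1 or more, those of the MYC targets (0.0671) and cholesterol synthesis (0.0647) lists ended.

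**Figure D3:**
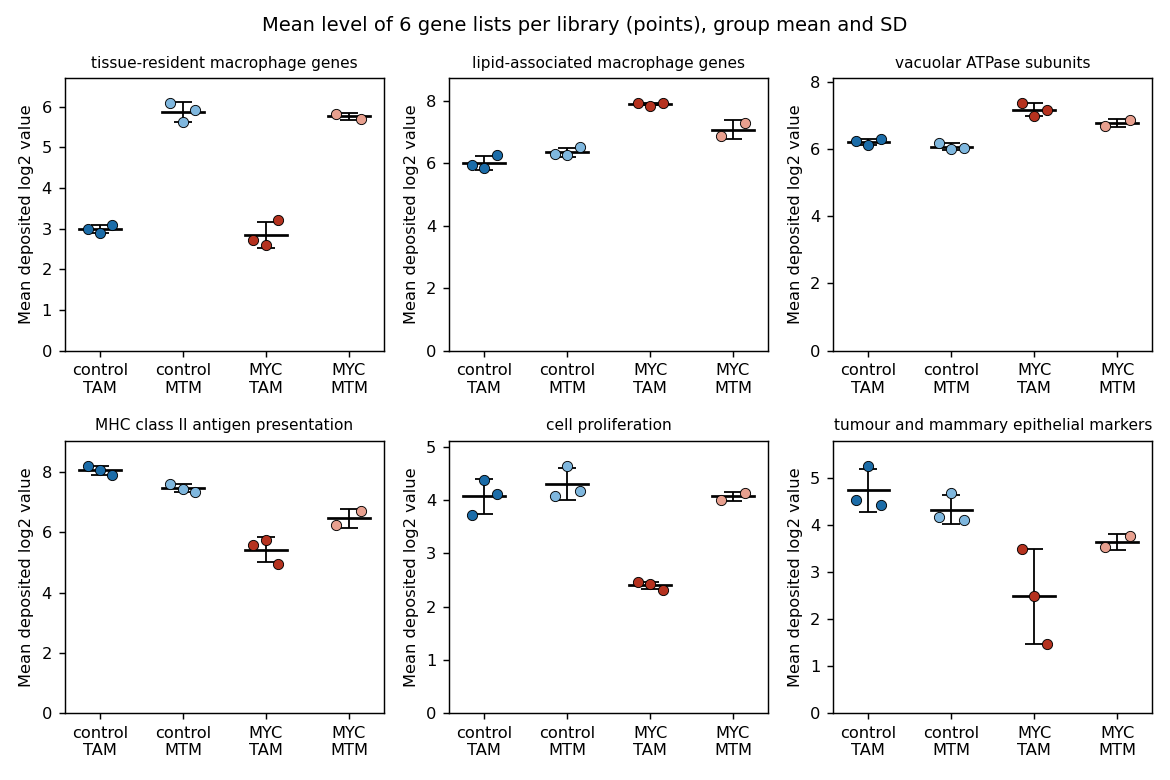
Mean deposited log2 level of the detected members of 6 gene lists in each of the 11 libraries; each point is a library, coloured by group. Proliferation genes are at 2.32 to 2.46 in the MYC TAM libraries and at 3.72 or more in all others, and epithelial markers are lowest in the same libraries, at 1.46 to 3.49.

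MTMs of MYC and control tumours were compared for the same question in the tissue macrophages. Some of the largest rises in TAMs were seen here at smaller size. Atp6v0d2 rose from 3.63 ± 0.52 to 8.25 ± 0.56, by 4.62 ± 0.35 (24.7-fold, adjusted p = 0.00123), Gpnmb by 4.29 ± 0.45 (19.6-fold), Fabp4 by 3.73 ± 0.48 and Klra3 by 2.90 ± 0.26. Saa3 rose by 5.11 ± 0.69, the neuropeptide gene Npy by 3.50 ± 0.33, the tetraspanin-like gene Tm4sf19 by 3.27 ± 0.30 and the Y-linked Ddx3y by 3.05 ± 0.20. The fibrinogen chain genes Fgb and Fgg fell by 4.21 ± 0.22 and 4.10 ± 0.34, the epithelial plaque gene Upk3a by 3.18 ± 0.27, Vcam1 by 3.49 ± 0.61 and the lectin gene Mgl2 by 3.24 ± 0.42. Fgb was alike in control TAMs (4.33, 4.24 and 3.85) and control MTMs (4.51, 4.08 and 4.18), and at most 0.37 in every MYC library. Whether RNA of Fgb, Fgg and Upk3a came from the macrophages or was carried over from other cells was not tested. Emr1 did not differ detectably (0.18 ± 0.29, adjusted p = 1.00).

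Few list members passed singly in MTMs, and no list held with an estimated correlation. Lysosomal genes had a median of 0.37 with 1 of 51 past the threshold (8 higher and 1 lower adjusted over the list alone; adjusted p = 3.52e-09, and adjusted p = 0.123 with an estimated correlation), Gla (1.58 ± 0.24). Glycolysis and hypoxia genes had a median of 0.36 (7 of 30 higher adjusted over the list alone; adjusted p = 2.03e-07, and adjusted p = 0.100 with an estimated correlation), with Hilpda (2.07 ± 0.29) and Bnip3 (1.08 ± 0.17) higher. Lipid-associated genes (median 0.37, adjusted p = 1.88e-06), vacuolar ATPase subunits (0.34, 9.30e-06), ribosomal proteins (0.28, 0.000611), MYC targets (0.14, 0.00103), adipocyte markers (0.14, 0.00116), autophagy (0.15, 0.00288), lipid efflux (0.17, 0.0464) and complement (0.08, 0.0478) were higher in MYC. MHC class II (-1.14, adjusted p = 2.31e-05), cholesterol synthesis (-0.35, 3.28e-05), epithelial markers (-0.79, 0.00693), T and NK markers (-0.53, 0.0103) and dendritic markers (-0.13, 0.0268) were lower. For these lists the adjusted p with an estimated correlation was 0.100 to 0.717. Epithelial markers were at 4.17, 4.68 and 4.11 in the control MTM libraries, above both MYC MTM libraries at 3.52 and 3.76.

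In MTMs 108 genes differed between the genotypes, 59 higher and 49 lower in MYC (105 with the mouse as a random block). The count was 68 and 65 without control TAM mouse 1 or 5, 52 and 35 without control MTM mouse 3 or 5, and 32 and 23 without MYC MTM mouse 2 or 4. Of the 27 named genes that passed, 8 passed without each library in turn, namely Atp6v0d2, Ddx3y, Fgb, Fgg, Klra3, Npy, Tm4sf19 and Upk3a. Gpnmb was lost without MYC MTM mouse 4 (adjusted p = 0.0599), Saa3 and Fabp4 without it (0.0688 and 0.140) or control MTM mouse 5 (0.0569 and 0.0556), Saa3 also without MYC MTM mouse 2 (0.166), and Mgl2 without MYC MTM mouse 2 (0.0797) or control MTM mouse 5 (0.0556). Bnip3, Gla, Hilpda and Vcam1 were each lost without MYC MTM mouse 4 (0.167, 0.211, 0.170 and 0.252) and without control MTM mouse 5 (0.0889, 0.0771, 0.0569 and 0.0862), and Bnip3, Gla and Vcam1 also without MYC MTM mouse 2 (0.319, 0.148 and 0.319), control MTM mouse 1 (0.0824, 0.0682 and 0.0674), control MTM mouse 3 (0.0803, 0.0679 and 0.0880) or control TAM mouse 1 (0.0555, 0.0533 and 0.0810). Vcam1 was lost too without control TAM mouse 3 (0.0516) or 5 (0.0840) or MYC TAM mouse 4 (0.0653). Complement lost its call without control MTM mouse 3 (0.156), MYC TAM mouse 2 (0.0611), 4 (0.0640) or 6 (0.0530), or MYC MTM mouse 2 (0.108), and lipid efflux without control TAM mouse 3 (0.0582), control MTM mouse 1 (0.0533) or 3 (0.139), MYC TAM mouse 4 (0.0526) or MYC MTM mouse 4 (0.0953). T and NK and dendritic markers lost it without MYC MTM mouse 2 (0.405 and 0.203), and epithelial markers without control MTM mouse 3 (0.0623). Complement and lipid efflux lost it after quantile normalisation too (0.212 and 0.196). Under the alternatives chosen after seeing the data, both lost it with the epithelial covariate (0.290 and 0.514), where the lipid efflux median was -0.04, and among genes with a mean of 1 or more (0.0881 and 0.0823), as did dendritic markers there (0.0513). Without MYC TAM mice 4 and 6 complement (0.0912) and the T and NK and dendritic markers (0.0746 each) lost it. With the covariate oxidative phosphorylation (0.16, adjusted p = 0.00437), ATF4 targets (0.02, 0.0405) and interferon response (-0.32, 0.0143) passed. Its levels did not overlap between control and MYC MTMs, so these values are extrapolations.

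The genotype difference was shared between the cell types. Of the 680 genes higher in MYC TAMs, 49 were also higher in MYC MTMs, against 2.30 if the sets were independent, and of the 2098 lower in MYC TAMs, 38 were also lower in MTMs, against 5.88. No gene passed in opposite directions. Across 9375 genes the differences correlated with r = 0.598 and rho = 0.493, across genes that are not independent replicates. The TAM and MTM libraries came from the same mice, so these sets share animals. They also rest on the same variance estimate per gene, which can raise the number shared above that of independent sets.

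**Figure D4:**
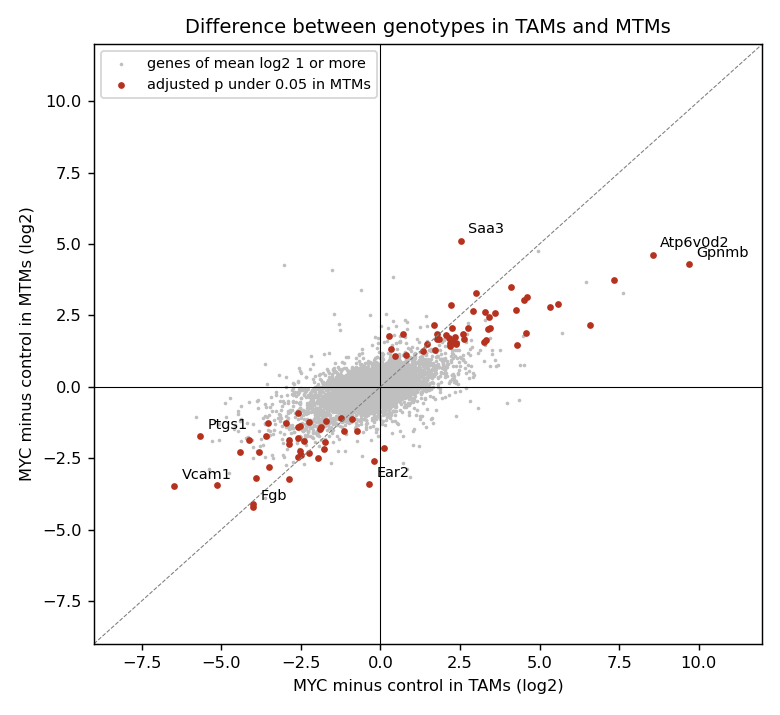
Log2 difference between MYC and control in TAMs (across) against that in MTMs (up) for 9375 genes with a mean of 1 or more; each point is a gene, and genes past the threshold in MTMs are coloured. Across these genes r = 0.598, and no gene passed in opposite directions.

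Whether the difference between TAMs and MTMs itself differed between genotypes was tested directly. Gpnmb was lower in control TAMs than MTMs and higher in MYC TAMs than MTMs, a difference of 5.40 ± 0.60 (adjusted p = 0.00754). Hpse (4.42 ± 0.50), Atp6v0d2 (3.93 ± 0.47) and Grap, an adaptor protein gene (3.62 ± 0.20, adjusted p = 0.000224), also went further toward TAMs in MYC mice. Tmem176a (-4.33 ± 0.49), Haao, an enzyme of tryptophan breakdown (-4.32 ± 0.45), Ptgs1 (-3.95 ± 0.32), the immunoglobulin gene Ighm (-3.81 ± 0.32), Siglece (-3.76 ± 0.44) and Zmynd15 (-3.67 ± 0.32) went further toward MTMs. Proliferation genes had a median of -1.54 (adjusted p = 3.16e-22, and adjusted p = 0.130 with an estimated correlation), and 6 of 33 passed (27 adjusted over the list alone). MHC class II genes had a median of -1.52 (adjusted p = 1.09e-07, and adjusted p = 0.129 with an estimated correlation), and lipid-associated genes 1.20 (adjusted p = 2.52e-08, and adjusted p = 0.106 with an estimated correlation). Vacuolar ATPase subunits had a median of 0.52 (adjusted p = 0.000122, and adjusted p = 0.106 with an estimated correlation).

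For this difference 216 genes passed, 42 higher and 174 lower. The share higher was 19.4%, and 29.5% after median centring (38 higher, 91 lower), which moved the median of all genes to 0.10. The mouse as a random block gave 325 genes and as a fixed block 31. The count was 26 and 30 without MYC MTM mouse 2 or 4, 120, 105 and 105 without control TAM mouse 1, 3 or 5, and 95 and 66 without control MTM mouse 1 or 5. Of the 38 named genes that passed, 7 did so without each library in turn, and Atp6v0d2 (adjusted p = 0.0572), Hpse (0.0505) and Siglece (0.0589) lost the call without MYC MTM mouse 2. With the fixed block the adjusted p of Tmem176a was 0.0610.

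Genes tied to lysosomal nutrient sensing were named before the data were examined. Rragd, a Rag GTPase subunit gene, was at 0.60 ± 0.12 in control and 2.73 ± 0.52 in MYC TAMs and rose by 2.13 ± 0.24 (adjusted p = 0.000467), and its difference in MTMs was 1.48 ± 0.27 (adjusted p = 0.0544). Tfeb differed between MYC and control by -0.16 ± 0.15 in TAMs and -0.07 ± 0.17 in MTMs, and Tfe3 by 0.26 ± 0.25 and -0.25 ± 0.29. The corresponding values were 1.24 ± 0.68 and -1.13 ± 0.76 for Sqstm1, -0.16 ± 0.27 and 0.44 ± 0.30 for Pikfyve, and -0.70 ± 0.34 and 0.61 ± 0.38 for Flcn, none past the threshold (adjusted p from 0.216 to 1.00). The Rag GTPase and TFEB/TFE3 machinery list passed in no comparison (smallest adjusted p = 0.330), nor did the PIKfyve list (0.0620), although it passed under some alternatives, among them the mouse as a random block for MYC against control MTMs (0.0344). S100a8, whose promoter drives the Cre, was at 3.26 ± 0.67 in control and 5.26 ± 0.85 in MYC TAMs (2.00 ± 0.57, adjusted p = 0.0430), and its adjusted p was 0.144 without control TAM mouse 5, 0.135 without MYC TAM mouse 2, 0.0984 without control TAM mouse 3, 0.0687 without MYC TAM mouse 6, 0.0652 without MYC MTM mouse 2, 0.0648 without MYC MTM mouse 4 and 0.0538 without control MTM mouse 3.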

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

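All tests of explanations below were chosen after the result was seen, except the regroupings of the libraries, which were planned.

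What drew attention was a test of the difference between the genotypes in how TAMs and MTMs differ, which 216 genes passed. Here toward TAMs or MTMs gives the sign of this difference, and not the cell type with the higher level. Adamdec1 was near the floor in the MYC TAM (0.02, 0.14 and 0.54) and MYC MTM libraries (0.27 and 0.15). Ear2 was low in the MYC TAM libraries (0.12, 0.23 and 0.29) and higher in the MYC MTM libraries (1.13 and 2.32). Of the named genes, those further toward TAMs in MYC mice were Gpnmb (5.40), F7 (4.81), F10 (4.56), Hpse (4.42), Atp6v0d2 (3.93), Cdo1 (3.84), Spp1 (3.83), Tnfrsf26 (3.76), Grap (3.62), Fabp4 (3.60) and Ear2 (3.05), in log2. Those further toward MTMs were Tmem176a (-4.33), Haao (-4.32), Ly6a (-3.98), Ptgs1 (-3.95), Ighm (-3.81), Siglece (-3.76), Adamdec1 (-3.72), Zmynd15 (-3.67), Slco2b1 (-3.59), Dgat2 (-3.57), Cd74 (-3.41), H2-Oa (-2.97), Slc7a5 (-2.90), Lpl (-2.87), Cfb (-2.82), Cdh1 (-2.58), Rrm2 (-2.46), Plk1 (-2.44), Emr1 (-1.99), Mcm2 (-1.98), H2-DMa (-1.72), Hspa1b (-1.56), Car9 (-1.52), Cad (-1.46), Mcm3 (-1.31), Irf8 (-1.17) and Pkm (-1.0045). Only 7 of these 38 kept the call without each library in turn. The others lost it most often without MYC MTM mouse 2 (30 genes, adjusted p up to 0.207) or mouse 4 (26 genes, up to 0.246). They also lost it without control MTM mouse 1 (19 genes), 3 (9) or 5 (22), control TAM mouse 1 (9), 3 (16) or 5 (20), and MYC TAM mouse 2 (14), 4 (8) or 6 (1).

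The same test passed for 15 lists. Their medians were 1.20 for lipid-associated genes, 0.52 for vacuolar ATPase subunits and 0.31 for alternative activation genes, and -1.54 for proliferation, -1.52 for MHC class II, -1.31 for epithelial markers, -0.85 for NF-kB mediators, -0.62 for MYC targets, -0.61 for glycolysis and hypoxia, -0.57 for ATF4 targets, -0.51 for complement, -0.50 for interferon response, -0.44 for T and NK markers, -0.43 for dissociation genes and -0.37 for dendritic markers. With an estimated correlation none passed (adjusted p from 0.106 to 0.772). Without single libraries the calls ended for dissociation genes (adjusted p from 0.0592 to 0.232 over control TAM mice 3 and 5, control MTM mice 1 and 3, MYC TAM mice 4 and 6, and MYC MTM mouse 4). They also ended for interferon response (0.0569 without control MTM mouse 1, 0.142 without MYC TAM mouse 4, 0.0583 without MYC MTM mouse 4), dendritic markers (0.143 without MYC MTM mouse 4) and alternative activation (0.0547 without control MTM mouse 5). Without MYC TAM mice 4 and 6 together, those of the epithelial markers (0.419), dissociation genes (0.767) and dendritic markers (0.0505) ended. With the epithelial covariate those of alternative activation (0.115) and dissociation genes (0.363) ended. Among genes with a mean of 1 or more those of interferon response (0.0701), T and NK markers (0.0784), dendritic markers (0.111) and dissociation genes (0.384) ended. Lists that had not passed and did with the covariate were ribosomal proteins (1.22), oxidative phosphorylation (0.39), monocyte markers (-0.39), engulfment receptors (-0.31), lipid efflux (-0.26) and PIKfyve machinery (-0.16). The covariate did not overlap between control and MYC libraries, so these values are extrapolations.

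Proliferation genes were lower in MYC than in control TAMs, in the libraries with the least epithelial RNA. Loss of carried-over tumour cell RNA as the whole cause could not be decided. With the epithelial level as a covariate the list mean still differed by -1.18 (95% interval -2.03 to -0.32), against -1.63 (-2.09 to -1.17) without it. But the covariate measures such RNA only indirectly, which can leave a difference behind. Its levels also did not overlap between control TAMs (4.42 to 5.25) and MYC TAMs (1.46 to 3.49). The TAMs were sorted as CD45 and F4/80 positive, gates meant to leave such cells out, yet epithelial RNA was present. As part of the cause it stays open, because the covariate moved the difference by 0.458, within these intervals, and the covariate follows the genotype. A few abundant genes taking reads from all others is argued against, as the list median lay -1.60 below that of all detected genes. Slower division of TAMs in MYC tumours is a biological explanation that stays open and untested.

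Vcam1 RNA was low in the MYC TAM libraries, which were sorted as Vcam positive. An exchange of TAM and MTM tubes in the MYC mice is argued against by Folr2, which was lower in the libraries labelled TAM by -6.22. Fewer macrophages in those libraries as the whole cause is argued against by 12 pan-macrophage genes, whose median difference was -0.0271. Of these, Cd68 (1.95), Lyz2 (1.39) and Ctss (0.90) rose and Csf1r (-2.57), Fcgr1 (-2.004), Emr1 (-1.81) and C1qa (-1.62) fell, each by less than Vcam1. A smaller loss of macrophages stays open, as the median of genes that moved both ways cannot exclude it. A different placing of the gate in the MYC mice, and surface protein that outlasts its RNA, stay open and were not tested.

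Y-linked transcripts were present in every MYC library, although the mice are described as female. Reads of X-linked homologues assigned to Y-linked genes, at a share set by their sequence, are argued against, as the lowest ratio of Y-linked to X-linked level in a MYC library was above the highest in a control library for each of 4 pairs, by a factor of 7.53 in the closest. Carried-over tumour cells of male hosts stay open as part of the source. As the whole source they were not decided by an interval, though values within mice 2 and 4 argue against them. The Y-linked mean minus the epithelial mean was higher in MYC TAM than in MYC MTM libraries by 2.18, but the 95% interval over the 5 libraries was -0.763 to 5.13. In the TAM and MTM libraries of mouse 2 the epithelial level was 3.49 and 3.52, and the Y-linked mean was 2.49 and 1.73. In those of mouse 4 the epithelial level was 2.48 and 3.76, and the Y-linked mean was 3.13 and 1.90. Y-linked RNA from such cells alone would follow their markers, and within mice 2 and 4 it did not. The MYC library with the lowest epithelial level (TAM mouse 6, 1.46) had a Y-linked mean of 2.89. The MYC library with the highest (MTM mouse 4, 3.76) had a Y-linked mean of 1.90. Male cells in the MYC libraries stay open as the source. The highest ratio to the X-linked homologue in a MYC library was 2.77 for Ddx3y, 0.989 for Eif2s3y, 0.780 for Kdm5d and 1.04 for Uty. In the control libraries the highest was 0.00419, 0.00209, 0.000783 and 0.0142. All 20 pairs of gene and MYC library lay above every control library, but these genes were picked for that pattern, so the count decides nothing. The sex of the donors is not given. The Y-linked transcripts follow the genotype, so an effect of whatever brought them and an effect of genotype stay open as explanations of every difference between MYC and control.

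For 3 libraries against 3 there are 10 splits, which is too few for a share under 0.05. In control TAMs against MTMs the real split gave 414 genes and the highest other split 2, and in MYC against control TAMs 2778 and 1; in each case 1 of the 10 splits, the real one, gave as many.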

How the results depend on the processing

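The covariate, the mean of 1 or more and the joint removal of MYC TAM mice 4 and 6 were chosen after seeing the data. No named gene that passed reversed under any alternative. The call was kept under every alternative in 30 of 34, 26 of 78, 41 of 76, 7 of 27 and 6 of 38 named genes in the 5 comparisons, in the order of the processing section. No filter changed nothing because the planned filter was void. For control TAMs against MTMs (414 genes) library weights gave 1032, a fit of only the groups compared 251, the fixed mouse block 255 and leaving out a library 216 to 537. For MYC TAMs against MTMs (784) the values were 126 for only the groups compared, 476 for the fixed block and 163 to 1029 without a library. For MYC against control TAMs (2778) they were 5029 for median centring, 1576 for only the groups compared, 858 for the epithelial covariate and 1734 to 2999 without a library. For MYC against control MTMs (108) library weights gave 890, only the groups compared 18, and leaving out a library 23 to 131. For the difference of differences (216) they were 129 for median centring, 380 for weights, 325 and 31 for the random and fixed block, 327 for a mean of 1 or more, 53 for the covariate, 333 without MYC TAM mice 4 and 6, and 26 to 302 without a library. Of the 75 list calls over the 5 comparisons, 3 ended with quantile normalisation, 0 with the random block, 18 with a mean of 1 or more and 13 without MYC TAM mice 4 and 6. With the covariate 11 of 70 ended. Passing lists numbered 3, 3, 0, 0 and 0 with an estimated correlation, against 11, 19, 15, 15 and 15 by camera. The direction of the camera test, which need not be that of the median, reversed for some lists. Without MYC TAM mouse 2 these were oxidative phosphorylation in MYC TAMs against MTMs (median -0.22, from -0.06, and 0.13 at most without another library), ribosomal proteins in MYC against control TAMs (-0.12, from 0.29, at most 0.70) and ribosomal proteins in the difference (-0.50, from -0.05, at most 0.37). The first and the last of these medians were below 0 before. With the covariate, they were engulfment receptors in MYC against control TAMs (-0.41, from 0.05) and PIKfyve machinery in the difference (-0.16, from 0.00263). Without MYC TAM mice 4 and 6, they were epithelial markers (0.00391, from -0.99) and dissociation genes (-0.0885, from -0.48) in MYC TAMs against MTMs, and the median of the dissociation genes kept its sign. The fits of fewer libraries and of only the groups compared have fewer residual degrees of freedom, and for the other alternatives the cause was not tested. Where leaving out a library left a group with 1, it was assumed to vary like the others. On simulated data with few changed genes, changes of a log2 of 1 were mostly missed, most of all in the difference of differences (6% recovered). Recovery was not measured with as many genes changed as passed in MYC against control TAMs (2778).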

Other observations

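The hypothesis test in this part was chosen after the result was seen. Some lists that did not pass as a whole between control and MYC TAMs had members past the threshold. Of 20 lipid efflux and LXR target genes 6 rose and 9 fell (7 and 10 adjusted over the list alone; median -0.40, camera adjusted p = 0.926), with Fabp4 higher (7.33) and Lpl lower (-3.60). Of 25 matrix protease and turnover genes 7 rose and 6 fell (median -0.01, adjusted p = 0.488), with cathepsin K higher (Ctsk, 6.46) and the collagenase gene Mmp13 lower (-5.39). Of 23 iron and heme genes 2 rose and 5 fell (median 0.04, adjusted p = 0.798), the rises Fth1 2.02 and Slc11a2 0.88 and the falls Slc40a1 -2.54, Trf -2.25, Nqo1 -2.23, Spic -2.14 and Steap4 -1.43. Of 33 genes of the Rag GTPase and TFEB/TFE3 machinery 5 rose and 3 fell (median -0.12, adjusted p = 0.714), the rises Rragd 2.13, Fnip2 2.25, Lamtor3 1.06, Fnip1 1.03 and Lamtor1 0.56 and the falls Rptor -1.28, Kptn -0.97 and Sec13 -0.51. Of 42 oxidative phosphorylation genes none rose and 1 fell, Cox5a -0.78 (median -0.02, adjusted p = 0.808), and with the epithelial covariate the list passed upward (median 0.56, adjusted p = 4.49e-06). That covariate did not overlap between control and MYC TAMs, so the value with it is an extrapolation. Of 13 neutrophil markers 3 rose and 3 fell (median 0.05, adjusted p = 0.399), the rises S100a8 2.00, Mmp8 2.02 and Cxcr2 0.16 and the falls Ltf -4.47, Lcn2 -4.19 and Il1r2 -2.56. Ltf and Lcn2 are also on the list of epithelial markers, which fell in this comparison. The members named here, apart from Fabp4, Lpl, Ctsk, Mmp13, Trf, Rragd and S100a8, were picked out after their values were seen.

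In the MYC mice, the Y-linked genes were higher in TAMs than in MTMs. The log2 difference was 1.46 ± 0.20 for Ddx3y (adjusted p = 0.00365) and 1.32 ± 0.29 for Eif2s3y (0.0367), past the threshold, and 0.54 ± 0.19 for Kdm5d (0.176) and 0.76 ± 0.36 for Uty (0.338), not past it. A larger share of male-derived cells among TAMs than among MTMs may account for this. On the linear scale the ratios of TAMs to MTMs were 2.97, 3.12, 1.98 and 2.55. They restate the difference that led to the hypothesis and give it no support, so it stays open. Male cells that transcribe these genes more in TAMs than in MTMs would give the same ratios, and the data do not tell these apart.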
